A study of Mus musculus with 4 samples.

How the data were processed

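Gene expression was measured on Affymetrix arrays, 1 array per sample, in cDC2 sorted from mouse spleen, 2 samples labelled wild type (WT) and 2 labelled Id2 knockout (Id2 KO). Per the labels' protocols, red blood cells were lysed, cDC2 were sorted by flow cytometry, total RNA was extracted on columns, and biotinylated cDNA was made with a NuGen Ovation PicoSL whole-transcriptome amplification system. Amplification of small RNA amounts can compress or shift the levels of some transcripts, and it was named for every sample.

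The deposited values are 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes, the tools were Affymetrix Expression Console and RMA, named without a version, a role or an order. RMA subtracts a modelled background, makes the distributions of the arrays equal at the level of single probes, and summarises the probes of a set on the log2 scale. The deposited intensity values reach from 5.19 to 18624, so they appear to have been returned from log2 to the linear scale, a step that no source used here records. The median intensities were 134 and 130 in the WT arrays and 128 and 132 in the arrays labelled Id2 KO. No sign of gene-wise centring was seen in the values. Scanner files and calls of probe sets above background were not used here, so a dim probe set has no measured background beside it, and the size of a difference is uncertain where the level of 1 group lies near or below the filter level. The array medians differ slightly, so the deposited distributions are not exactly equal. Where arrays are scaled to each other, a change in the total RNA per cell is largely removed, and a large change in a few bright genes can shift the others slightly.

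The log2 of each intensity was taken before all tests, without a pseudocount. Gene names came from the annotation table of the array platform. Of 28853 probe sets, 21789 had 1 gene symbol, 1621 had several and 5443 were not listed there, and only those with 1 symbol were named. They stood for 19938 genes, and 21698 of the 21789 probe sets matched a gene table of the mouse assembly GRCm38.p6, used for older symbols, chromosomes and neighbouring genes. No genome build was given in the sources used here, so coordinates are not printed. For a gene with several probe sets the brightest was used. Among the 64 changed genes with several probe sets, 6 had a probe set of the opposite sign, namely Ddx3x, E2f3, Hdac4, Itgad, Kcnma1 and Tmem154.

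Genes with a mean above the 40th percentile over the 4 arrays (log2 6.77) were tested, 11963 in all. The comparison was Id2 KO minus WT, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 2 residual degrees of freedom per gene, to which the moderation added 6.77, with a prior SD of 0.0887 on the log2 scale. Intervals are 95% intervals from this fit, not adjusted for the number of genes. Adjusted p-values in the text are limma's unless stated. The number of arrays limits the precision.

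The 30 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists cover cDC2 and other dendritic cell types, the Id and E protein network, cell functions, and markers of other cells that a spleen sort could hold. The 28 lists with at least 5 tested members were tested with limma's camera and a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry stand beside it. Fry asks whether the genes of a list move, on balance, one way and does not set them against other genes. Named genes were the 15 with the largest change in each direction among genes past the threshold whose groups did not overlap, Id2 and the Id and E protein network, and from each list the 4 members with the largest change and those past the threshold. Predicted and non-coding genes and receptor gene segments were counted but not named, apart from Xist, which the list of sex-linked genes holds. Gene families named by symbol, the neighbours of Id2 and a few single genes were chosen after the values were seen, as is said where they appear.

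The procedure was tested on simulated data with the means of the 11963 genes and the fitted spread, in 20 simulations with 200 changed genes each. It recovered 8.6% of genes changed 1.25-fold, 85% at 1.5-fold, 99% at 2-fold and 100% at 3-fold, and 5.34% of its calls were unchanged genes. Each gene was drawn independently there, without variation shared between genes. These shares therefore need not hold for the real arrays, where genes can vary together. For lists, 1 list had all its members moved up by the same amount. The preset correlation called this shifted list in 100% of the simulations, the estimated correlation in 0% and fry in 75%. Of lists without a shift, the preset correlation called 0.185% where genes varied independently and 36.6% where the members of a list shared variation between arrays. Camera with an estimated correlation and fry called 0% of the latter. A list call with the preset correlation can therefore come from variation shared by its genes in these 4 arrays, and a missing call with the estimated correlation says little in a design of this size.

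Alternatives were no filter on dim genes or one at the 60th percentile, the mean of a gene's probe sets, renewed quantile normalization, centring of each array on its median over the tested genes, an intensity-trended or robust prior, array weights, the replicate number as a block, each array left out in turn, limma's treat against a fold of 1.2, a fold of at least 2, and an adjusted p threshold of 0.1. Where 1 array of a group is left out, the lone array is assumed to vary like the other group. A crossed pairing of the replicate numbers and a fit without X- and Y-linked genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9.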

Results

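Gene expression was compared between wild-type (WT) and Id2 knockout (Id2 KO) splenic cDC2, to describe how the transcriptomes of the groups with these labels differ. The cDC2 are conventional dendritic cells that carry Sirpa and, in most cases, Itgam (CD11b), and that present antigen mainly to CD4 T cells. Id2 is a helix-loop-helix protein without a DNA-binding region that binds E proteins such as those encoded by Tcf3, Tcf4 and Tcf12 and keeps them from DNA. The cells were sorted from the spleens of chimeric mice with a Zbtb46-GFP reporter, in which a fluorescent protein marks cells that express Zbtb46, a transcription factor of conventional dendritic cells. A sentence of the series' design text also names bone marrow as the source, whereas the sample labels name the spleen throughout. Each group held 2 arrays, and their median intensities were 134 and 130 in WT and 128 and 132 in Id2 KO. The labels do not say whether the replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical.

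Id2 itself was only slightly lower in the arrays labelled Id2 KO. Its log2 intensity was 9.14 and 9.08 in the WT arrays and 8.71 and 8.97 in the arrays labelled Id2 KO, a mean difference of -0.27 (95% interval -0.50 to -0.04 before adjustment, n = 2 per group) that did not pass the test (limma, adjusted p = 0.172). With KO replicate 2 left out the difference was -0.40 and passed (adjusted p = 0.0326), and with KO replicate 1 left out it was -0.14 (adjusted p = 0.627), the ends of the range over the alternatives. Among all 19938 genes, Id2 stood at percentiles of 77.0 and 81.9 in the arrays labelled Id2 KO and of 84.8 and 83.2 in WT. A single probe set measured Id2, and the part of the gene deleted in the knockout was not given in the sources used here, so the probe set may lie outside it and then checks nothing. The groups are therefore called WT arrays and arrays labelled Id2 KO, and every direction below rests on those labels.

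The groups also differed in sex-linked genes. Xist, the RNA that silences an X chromosome in female cells, was at log2 11.96 in both WT arrays and at 6.67 and 6.68 in the arrays labelled Id2 KO (difference -5.28, 95% interval -5.46 to -5.11, adjusted p = 3.66e-09). Kdm5d, a Y-linked gene, rose from 5.63 ± 0.14 to 8.29 ± 0.29 (SD, n = 2 each; adjusted p = 2.04e-05). Y-linked Uty lay below the intensity filter with means of 4.61 and 7.85, as did Eif2s3y with 3.89 and 5.18. Genotype and these sex-linked levels split the 4 arrays the same way, so they cannot be told apart in any comparison here. Of 330 tested X-linked genes, 24 changed, 14 higher and 10 lower, a share slightly below the 8.04% of all tested genes.

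**Figure D1:**
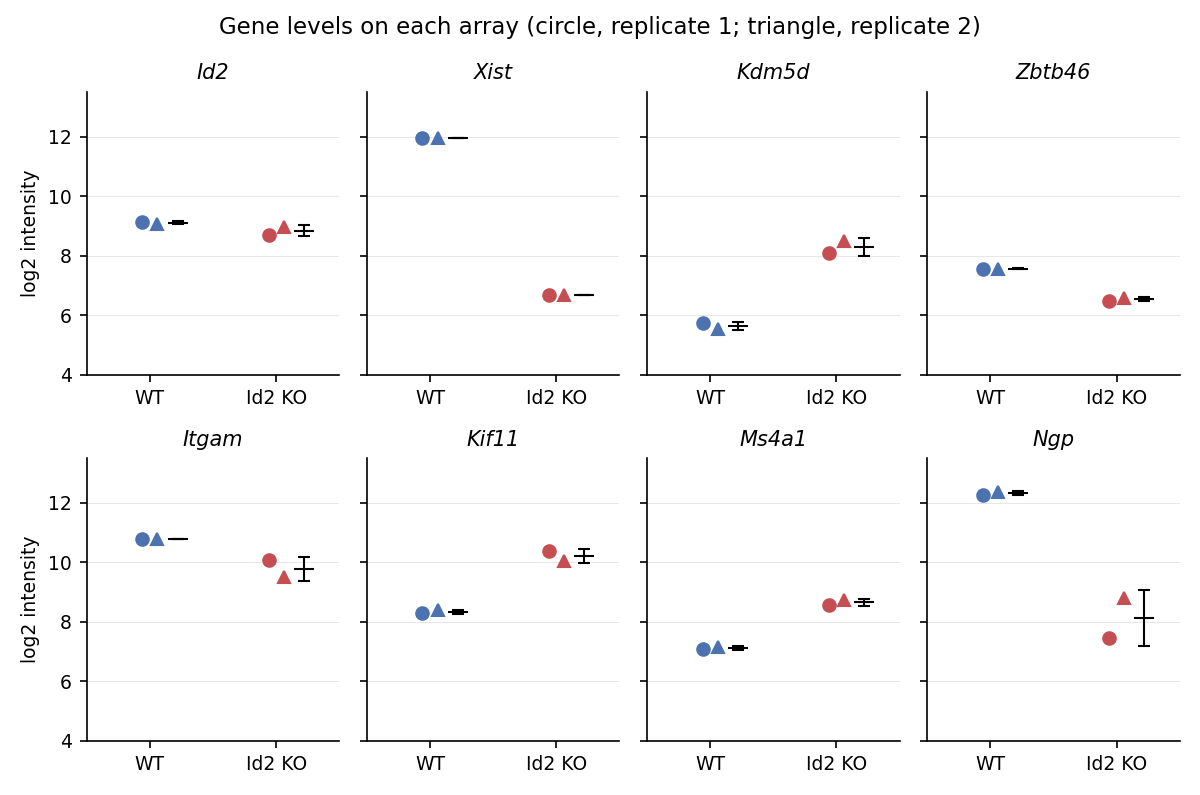
Log2 intensity of 8 genes on each array, WT in blue and arrays labelled Id2 KO in red, with circles for replicate 1, triangles for replicate 2, and the group mean with its SD as black bars. Id2 differed by -0.27, Xist by -5.28, and the replicates of Ngp in the arrays labelled Id2 KO lay apart, at 7.45 and 8.79.

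Of 11963 tested genes, 962 changed, 661 of them higher and 301 lower in the arrays labelled Id2 KO (68.7% higher). With each array centred on its median, 1043 genes changed and the split was 573 higher and 470 lower (54.9% higher). At least 2-fold changes numbered 137 higher and 40 lower. Most of the largest rises after Kdm5d were in genes of mitosis, among them Mastl (1.92 on the log2 scale), Kif11 (1.87), Anln (1.86) and Nusap1 (1.77), followed between 1.73 and 1.61 by Hmmr, Prc1, Knl1, the B cell list's IgM receptor gene Fcmr (1.67), Kif18b, Foxm1, Ccna2, Kif15, Plk1 and the DNA repair gene Neil3. The largest falls after Xist were in genes of the fixed neutrophil list, led by Ngp (-4.19) and Lcn2 (-4.19). The named genes outside that list were Chil3 (-2.02) of the monocyte list, the pore-forming protein gene Mpeg1 (-1.93), the haptoglobin gene Hp (-1.64), Anxa1 (-1.57) and the peptide transporter gene Slc15a2 (-1.51). Whether their falls come from the same cells as those of the neutrophil list was not tested. Leaving out WT replicate 1 gave 459 changed genes (454 of them among the 962) and leaving out WT replicate 2 gave 627 (575 among the 962). Without X- and Y-linked genes, a choice made after seeing the data, 942 changed, 649 higher and 293 lower.

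**Figure D2:**
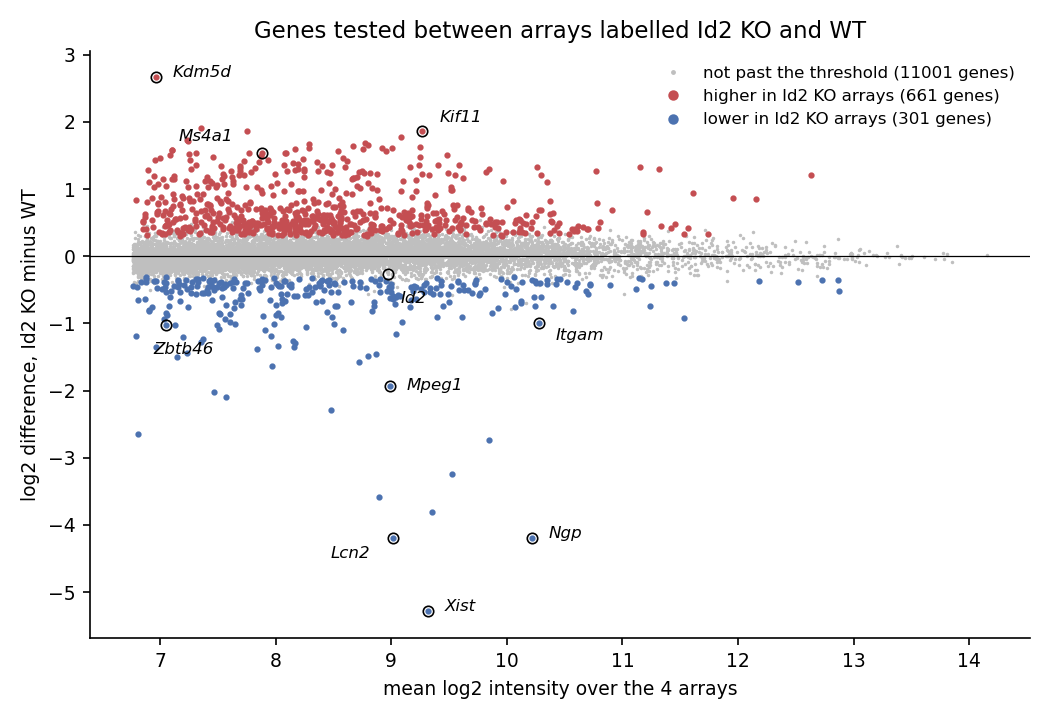
Log2 difference (arrays labelled Id2 KO minus WT) against the mean log2 intensity over the 4 arrays, 1 point per tested gene. The 661 higher genes are red, the 301 lower genes blue, the others grey, and 10 genes are circled and named.

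Cell cycle genes were higher throughout in the arrays labelled Id2 KO. Of 29 tested members of the fixed list, 28 rose and none fell, and all 29 were higher when adjusted over the list alone, with a median log2 difference of 1.24. Among the regulators of mitosis, the kinesin gene Kif11 rose from 8.34 ± 0.07 to 10.20 ± 0.22 (SD, n = 2 each; 3.65-fold, adjusted p = 4.26e-05), the cyclin gene Ccna2 rose by 1.63, the kinase gene Plk1 by 1.61 and the topoisomerase gene Top2a by 1.60. The proliferation marker Mki67 rose by 1.28 (2.42-fold). The nucleotide synthesis genes Rrm1 (1.24), Tyms (1.12) and Rrm2 (1.09) rose, the replication helicase genes Mcm2 to Mcm7 rose by between 0.62 (Mcm6) and 0.98 (Mcm7), and the mitotic gene Ube2c rose by 0.62. The DNA clamp gene Pcna at 0.36 did not pass (adjusted p = 0.0676). All 29 were higher in KO replicate 1 than in KO replicate 2, by a median of 0.38. The list shifted up in limma's camera (adjusted p = 1.86e-33), a call that was lost with an estimated correlation (adjusted p = 0.334). The calls of Mcm2, Mcm3, Mcm4, Mcm5, Mcm6, Mcm7 and Ube2c were lost without WT replicate 1, which left 21, those of Mcm2, Mcm4, Mcm5 and Mcm6 also without WT replicate 2, and those of Mcm2 and Mcm4 also without KO replicate 1. Neutrophil genes (median -2.47) and Xist were lower, and B cell genes (median 0.59) and Kdm5d higher, in the same arrays.

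Genes of the B lineage were higher in the arrays labelled Id2 KO. Of 15 tested members of the B cell list, 10 rose, 1 fell and 4 did not pass (10 and 2 adjusted over the list alone), with a median difference of 0.59. The surface protein gene Ms4a1 (CD20) rose from 7.12 ± 0.07 to 8.65 ± 0.11 (SD, n = 2 each; 2.89-fold, adjusted p = 4.26e-05), the IgM receptor gene Fcmr by 1.67, the complement receptor gene Cr2 by 1.28, the transcription factor gene Pax5 by 1.27, the receptor signalling gene Cd79a by 1.27 and the IgE receptor gene Fcer2a (CD23) by 1.03. Fcrla (0.69) and the transcriptional coactivator gene Pou2af1 (0.59) rose as well. Cd22, an inhibitory receptor that dendritic cells can also carry, fell by 0.56. Ighm, the constant region of IgM and among the most abundant transcripts of B cells, was at 7.71 ± 0.06 in WT, and its difference of 0.28 did not pass (adjusted p = 0.316), although it did without KO replicate 1 (adjusted p = 0.0111). These Ighm values are of its brightest probe set. Another Ighm probe set differed by 0.38 without overlap of the groups, and a dim one by -0.04. Probe sets whose annotation includes Iglc1 differed by 1.07 and 1.32, and those including Igkc by between 0.10 and 0.51. The B cell list shifted up (camera adjusted p = 8.94e-07, and 0.334 with an estimated correlation). With genes above the 60th percentile (5 of 9 higher, median 0.34) the list did not pass in camera (adjusted p = 0.0611, the highest of its alternatives, which began at 1.03e-11). Cd79b (0.40) and Blk (0.34) lost their calls without WT replicate 1 and without WT replicate 2, and Blk also without either KO replicate and under both scalings. Plasma cell genes did not shift (adjusted p = 0.317), although Prdm1, the regulator of plasma cell differentiation, rose by 0.55, as 1 of 6 tested (2 higher adjusted over the list alone), with its call lost without WT replicate 1.

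Part of the list of early lymphoid genes and E protein targets moved the same way. Of 9 tested members 5 rose and none fell (5 and 0 adjusted over the list alone), with a median of 0.49 that depends on the filter, at 0.03 over 13 members without one (4 higher) and 0.88 over the 4 above the 60th percentile. They were Ly6d, a surface marker of early lymphoid and plasmacytoid dendritic cell (pDC) progenitors (1.31), Cd79a (1.27), the signalling adaptor gene Blnk (2.30-fold), the adaptor gene Lax1 (0.83) and the interleukin 7 receptor gene Il7r (0.49), whose call was lost without WT replicate 1 and without KO replicate 2. Of the 9, 3 are in another list too, Cd79a in that of B cells and Ly6d and Blnk in that of pDC. The recombinase genes Rag1 and Rag2 lay below the filter, and the pre-T cell receptor gene Ptcra at -0.08 did not pass (adjusted p = 0.673). Igll1 (0.02), Vpreb1 (-0.16) and Notch1 (0.06) did not pass either. The list shifted up (camera adjusted p = 0.00143; adjusted p = 0.334 with an estimated correlation). Of 19 tested pDC genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone): Ly6d and Blnk again, the transcription factor gene Spib (1.07), the lectin gene Siglech (0.56) and Pacsin1 (0.34) rose, and the phospholipid transfer protein gene Pltp fell by 0.77. The pDC list did not shift (adjusted p = 0.213), but it did without KO replicate 1 (adjusted p = 0.0362) and without X- and Y-linked genes (adjusted p = 0.0281), in a range over the alternatives up to 0.854. Tcf4, the E protein gene of pDC, did not pass (-0.07, adjusted p = 0.686). The call of Pacsin1 was lost with each array left out and with median-centred arrays, and that of Siglech without WT replicate 2.

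Genes of the cDC2 list were lower on balance. Of 17 tested members of the cDC2 list, 6 fell, 3 rose and 8 did not pass (10 and 3 adjusted over the list alone), with a median of -0.29. The integrin gene Itgam (CD11b) fell from 10.77 ± 0.00 to 9.78 ± 0.41 (SD, n = 2 each; 2.00-fold lower, adjusted p = 0.00479), the lectin gene Clec4a3 by 0.90, the coreceptor gene Cd4 by 0.84, Clec4a1 by 0.58, Clec4a2 by 0.41 and the transcription factor gene Klf4 by 0.41. The adhesion gene Esam (0.53), the sphingosine receptor gene S1pr1 (0.42) and the NF-κB gene Relb (0.42) rose. Sirpa at -0.23 (adjusted p = 0.131) and Irf4 at -0.18 (adjusted p = 0.408) did not pass. The list shifted down (camera adjusted p = 0.00101; adjusted p = 0.334 with an estimated correlation). Neutrophils, monocytes and macrophages also carry Itgam, and the lists of their markers had medians of -2.47, -0.28 (monocyte) and -0.48 (red pulp macrophage) in the same arrays. Itgam, Clec4a3 and Cd4 passed with each array left out. Without WT replicate 1 the list held 4 lower and 0 higher genes, and without WT replicate 2 it held 3 and 1. The calls of Clec4a1 and Clec4a2 were also lost without KO replicate 1, those of Relb and Klf4 without KO replicate 2, and that of Relb under both scalings (adjusted p = 0.0658 with renewed quantile normalization and 0.0534 with median-centred arrays).

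Splenic cDC2 include subsets with high and low Esam, which were not sorted apart here, and the lists of their genes were not tested against each other. Genes of the ESAM-low subset, which shares genes with monocytes, counted 5 lower and 2 higher among 10 tested (6 and 2 adjusted over the list alone), with a median of -0.45, and 4 lower and 1 higher among 13 without a filter, with a median of -0.11. The Fc receptor gene Fcgr3 fell by 0.98, the lipopolysaccharide coreceptor gene Cd14 by 0.88, the lysozyme gene Lyz2 by 0.72, Clec4a1 by 0.58 and Clec12a by 0.53, while the G-CSF receptor gene Csf3r rose by 0.82 and S100a4 by 0.45. Of the 10, 7 are in another list too. Cd14 and Lyz2 are in that of monocytes, as are Csf1r (0.04) and Cx3cr1 (0.09), which did not pass. The monocyte, macrophage and neutrophil lists had medians of -0.28, -0.48 and -2.47 in the same arrays. The list shifted down (camera adjusted p = 0.0143; adjusted p = 0.334 with an estimated correlation), but not with genes above the 60th percentile (adjusted p = 0.0549, the highest of its alternatives, which began at 0.0024). Genes of the ESAM-high subset, which depends on Notch signalling, counted 3 higher and 2 lower among 11 (4 and 3 adjusted over the list alone) and did not shift (adjusted p = 0.859). Esam (0.53), the lymphotoxin gene Ltb (0.42) and the Notch regulator gene Dtx1 (0.31) rose, while Cd4 and the Notch target gene Hes1 (-0.47) fell. The calls of Clec4a1, Clec12a, Hes1 and S100a4 were lost without WT replicate 2, those of Esam, Ltb and S100a4 without WT replicate 1, those of Clec4a1 and S100a4 without KO replicate 1, and that of Dtx1 with each array left out and under both scalings.

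Zbtb46, the gene behind the reporter, fell from 7.56 ± 0.01 to 6.54 ± 0.07 (SD, n = 2 each; 2.03-fold lower, adjusted p = 1.35e-04). Its mean in the arrays labelled Id2 KO lay below the filter level, so the size of this fall is not settled. The sample labels do not give the reporter genotype of each group, and an effect of the reporter on Zbtb46 was not tested. Zbtb46 was the single changed gene among 16 tested genes of conventional dendritic cells in general (1 lower adjusted over the list alone). The integrin gene Itgax (CD11c) differed by -0.01 (95% interval -0.19 to 0.17), the cytokine receptor gene Flt3 by 0.11 (-0.17 to 0.39) and the peptidase gene Dpp4 by 0.19 (-0.04 to 0.41). The list's median was 0.05, its mean -0.02 and its test pointed down without passing (adjusted p = 0.856), and with median-centred arrays the median was -0.00. Of 16 tested genes of MHC class II and antigen processing, Ctse, an endosomal protease gene, fell by 1.46 (adjusted p = 7.66e-04) and no other passed, also adjusted over the list alone. H2-Ab1 (-0.03), H2-Eb1 (-0.01) and Cd74 (-0.02) lay within 0.05 of 0, and the list did not shift (adjusted p = 0.139). Of 15 tested genes of MHC class I presentation, Nlrc5, a transactivator of these genes, rose by 0.42 and no other passed (1 adjusted over the list alone; list adjusted p = 0.139), although the list shifted up without a filter (adjusted p = 0.0253, in a range up to 0.385). The call of Nlrc5 was lost without WT replicate 1 and with the mean of a gene's probe sets.

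Neutrophil genes had the lowest median difference of the 30 fixed lists. Of 14 tested members 13 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -2.47. The granule genes Ngp (-4.19), Lcn2 (-4.19), Ltf (-3.59), Camp (-3.24), Mmp8 (-2.65) and Retnlg (-2.29) fell, as did S100a8 (-3.81) and S100a9 (-2.73), which encode calprotectin. Ngp was at 12.26 and 12.36 in the WT arrays and at 7.45 and 8.79 in the arrays labelled Id2 KO (adjusted p = 1.27e-04). The primary granule genes Mpo (-2.09), Elane (-1.38) and Prtn3 (-1.21) and the chemokine receptor gene Cxcr2 (-1.44) fell as well. Csf3r, which this list shares with the ESAM-low list, rose. The list shifted down (camera adjusted p = 1.13e-25; adjusted p = 0.334 with an estimated correlation), and all 14 calls held with each array left out. In the arrays labelled Id2 KO, 9 of the 14 still lay above the filter level on both arrays, while Mmp8, Mpo, Prtn3, Cxcr2 and, on KO replicate 1, Lcn2 lay below it. No background was measured, so the sizes of these falls and their order are not settled.

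Some genes of other myeloid and erythroid cells were lower in the same arrays, while other members of their lists did not pass. Of 13 tested red pulp macrophage genes 8 fell and none rose (10 and 0 adjusted over the list alone; median -0.48), with the iron exporter gene Slc40a1 at -1.19, the complement genes C1qc at -1.02, C1qa at -1.01 and C1qb at -0.88, and the receptor kinase gene Axl at -0.86, followed by Trf (-0.70), Vcam1 (-0.48) and Adgre1 (-0.34). Of 14 tested monocyte genes 6 fell and none rose (7 and 0 adjusted over the list alone; median -0.28, and -0.12 above the 60th percentile), with Chil3 at -2.02, Cd14 at -0.88, Lyz2 at -0.72 the fibronectin gene Fn1 at -0.67, the Fc receptor gene Fcgr4 at -0.67 and Lyz1 at -0.46. Of 6 tested erythroid and platelet genes 3 fell, all of them erythroid (3 adjusted over the list alone; median -0.32). These were the anion exchanger gene Slc4a1 (-1.49), the haem synthesis gene Alas2 (-0.94) and the carbonic anhydrase gene Car2 (-0.56), while the platelet genes Ppbp, Itga2b and Gp9 lay between -0.08 and 0.00. The macrophage, monocyte and erythroid lists shifted down (camera adjusted p = 7.55e-10, 1.49e-06 and 6.32e-04; adjusted p = 0.334 with an estimated correlation for each). The calls of Car2, Fcgr4, Lyz1 and Adgre1 were lost without WT replicate 1, those of Vcam1, Lyz1 and Adgre1 without WT replicate 2, and those of Lyz1 and Adgre1 without KO replicate 1.

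Immediate early and stress genes, which respond within minutes to handling of cells, fell in 6 of 24 tested cases and rose in none (10 and 0 adjusted over the list alone; median -0.21). The heat shock genes Hspa1a and Dnajb1 fell by 0.92 and 0.74, Klf2 by 0.43 and the stress response factor gene Atf3 by 0.39. Jun and Fosb fell by 0.36 and 0.35, and the abundant Fos (-0.21) and Egr1 (-0.01) did not pass. The list shifted down (camera adjusted p = 7.68e-07; adjusted p = 0.334 with an estimated correlation), but of the 6 genes only Hspa1a and Dnajb1 passed without WT replicate 1 or without WT replicate 2, and the calls of Atf3, Jun and Fosb were lost without KO replicate 1 and that of Fosb also without KO replicate 2. With renewed quantile normalization 8 fell and with median-centred arrays 9, but 3 fell without a filter and 3 with the replicate block. Of 25 tested type I interferon response genes, Rsad2 fell by 0.53 and no other passed (1 lower adjusted over the list alone; median -0.10), with its call lost without WT replicate 1. With renewed quantile normalization 3 of these genes fell, Oas3 and Oasl2 among them, and 4 fell with median-centred arrays, 4 with the crossed replicate block and 4 without KO replicate 1. That list shifted down (camera adjusted p = 0.00861; adjusted p = 0.66 with an estimated correlation), a call lost without WT replicate 2 (adjusted p = 0.0648) and without KO replicate 2 (adjusted p = 0.258, the highest of its alternatives, which began at 7.58e-05).

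Among maturation genes, 6 of 24 tested rose and 1 fell (6 and 3 adjusted over the list alone), but 3 rose and 1 fell with renewed quantile normalization and 3 rose and 3 fell with median-centred arrays. The actin-bundling gene Fscn1 rose from 8.91 ± 0.36 to 10.27 ± 0.30 (SD, n = 2 each; 2.56-fold, adjusted p = 0.00153), the interleukin 12 subunit gene Il12b by 0.87, the cytokine signalling inhibitor gene Socs2 by 0.80, Relb by 0.42, Icam1 by 0.41 and the chemokine receptor gene Ccr7 by 0.35, while Il1b fell by 0.52. Costimulatory Cd80 (0.19), Cd86 (0.11) and Cd40 (0.05) did not pass, and the list did not shift (adjusted p = 0.174), but it did without KO replicate 1 (adjusted p = 0.0129) and without a filter (adjusted p = 0.00504), in a range up to 0.55. Without WT replicate 1, 5 of the 6 rises lost their calls and that of Fscn1 did not, and 4 lost theirs without WT replicate 2 and 3 without KO replicate 2. Relb, Icam1 and Ccr7 lost theirs under both scalings. Of 18 tested Toll-like receptor and adaptor genes, Cd14, Tlr3 (-0.73) and Tlr2 (-0.59) fell and Ticam2 (0.39) rose (3 and 3 adjusted over the list alone; list adjusted p = 0.80). Cd14 is also in the monocyte list, and the monocyte and neutrophil lists had medians of -0.28 and -2.47 in the same arrays. The calls of Tlr2 and Ticam2 were lost without WT replicate 1 and without WT replicate 2, and that of Ticam2 also without KO replicate 2 and under both scalings. The median of the Toll-like receptor and adaptor list was 0.03, its mean -0.04 and its test pointed down. Of 18 tested chemokine receptor and adhesion genes, Cd44 (-0.74) and Cxcr3 (-0.43) fell, and Itgb1 (0.53), Esam, S1pr1, Icam1 and Ccr7 rose (5 higher and 4 lower adjusted over the list alone; list adjusted p = 0.717). Without WT replicate 1, Cd44 was the single call left, and without WT replicate 2 those of Ccr7, Cxcr3, S1pr1 and Icam1 were lost. Under both scalings the list held 3 higher and 3 lower genes, with the calls of Icam1 (adjusted p = 0.0646 and 0.0658) and Ccr7 (adjusted p = 0.0879 and 0.0957) lost.

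Cholesterol synthesis genes rose in 4 of 18 tested cases and fell in none (7 and 1 adjusted over the list alone; median 0.18). They encode enzymes of the pathway, with Hmgcs1 at 0.54, Pmvk at 0.46, Fdft1 at 0.43 and Sqle at 0.34. The list shifted up (camera adjusted p = 0.00502; adjusted p = 0.558 with an estimated correlation), with the call lost without KO replicate 1 (adjusted p = 0.054, the highest of its alternatives, which began at 4.44e-05), and that of Sqle lost with median-centred arrays. Of its members, 0 passed in limma without WT replicate 1, 1 without WT replicate 2, 2 without KO replicate 1 and 7 without KO replicate 2, and Tm7sf2 fell under both scalings. In the glycolysis and hypoxia list, Vegfa (-0.67), the lactate transporter gene Slc16a3 (-0.45) and the glucose transporter gene Slc2a1 (-0.40) fell among 17 tested (3 lower adjusted over the list alone), and without WT replicate 1 only Vegfa passed. Without KO replicate 2, Pfkp, Tpi1 and Pgk1 rose and 2 genes fell, and the call of Slc2a1 was lost there and without WT replicate 2. Its median was 0.09, its mean -0.03 and its test pointed down without passing (adjusted p = 0.613). Oxidative phosphorylation genes counted 0 changes in limma among 27 tested (0 adjusted over the list alone; 1 at an unadjusted p below 0.05; list adjusted p = 0.261), although the list shifted up without KO replicate 2 (adjusted p = 0.0107, in a range up to 0.764). Apoptosis regulators counted 0 among 15 (0 adjusted over the list alone; 9 at an unadjusted p below 0.05, in both directions), with a median of -0.01 and a mean of 0.02, while Bid fell under both scalings and Fas rose with renewed quantile normalization, and 1 gene rose without WT replicate 2 and without either KO replicate, and 3 with the crossed replicate block (list adjusted p = 0.796).

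Markers of cDC1, T cells, NK and innate lymphoid cells, and basophils gave few calls. Of 14 tested cDC1 genes, Tlr3, Cd24a (-0.50) and Snx22 (-0.45) fell and the chemokine gene Cxcl9 (0.62) rose (3 and 1 adjusted over the list alone; list adjusted p = 0.141), although the list shifted down without a filter (adjusted p = 0.0122, in a range up to 0.414). Xcr1 and Clec9a, which mark cDC1, lay below the filter, and only Tlr3 passed with each array left out. Of 11 tested T cell genes Cd3d fell by 0.43 (1 lower adjusted over the list alone; list adjusted p = 0.139; 1 higher without KO replicate 2), and of 6 tested genes of NK and innate lymphoid cells Klrd1 fell by 0.40 (2 lower adjusted over the list alone; list adjusted p = 0.17). The calls of Cd3d and Klrd1 were lost without WT replicate 1 and without WT replicate 2, that of Klrd1 also without KO replicate 1, while the NK list shifted down without WT replicate 1 (adjusted p = 0.0321, in a range from 0.0213 to 0.626). Of 3 tested basophil and mast cell genes the histidine decarboxylase gene Hdc fell by 0.85 (2 lower adjusted over the list alone), and that list was too small to test.

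In the Id and E protein network, 1 of 22 tested genes passed. Runx1, a transcription factor of blood cell development, rose by 0.41 (adjusted p = 0.0143), a call lost without WT replicate 1, without WT replicate 2 and without KO replicate 1 (adjusted p = 0.115, 0.0683 and 0.0518, in a range that began at 0.00813). The E protein genes Tcf3 (0.08), Tcf4 (-0.07) and Tcf12 (-0.11) did not pass, nor did the dendritic cell regulators Irf8 (0.14), Batf3 (0.05), Zeb2 (0.04), Nfil3 (0.18), Bcl6 (0.04) and Spi1 (0.07). Zbtb16 at -0.31 and Mycl at -0.24 did not pass (adjusted p = 0.0641 and 0.145), but passed with renewed quantile normalization (adjusted p = 0.0491 and 0.0443, in ranges up to 0.308 and 0.454). Zbtb16 also passed with median-centred arrays (adjusted p = 0.0388), with the crossed replicate block (adjusted p = 0.0367) and without KO replicate 2 (adjusted p = 0.0409). The other Id genes, Id1, Id3 and Id4, lay below the filter with differences of -0.04, -0.03 and -0.04. The list counted 1 higher and 0 lower genes adjusted over the list alone, and it did not shift (adjusted p = 0.281).

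**Figure D3:**
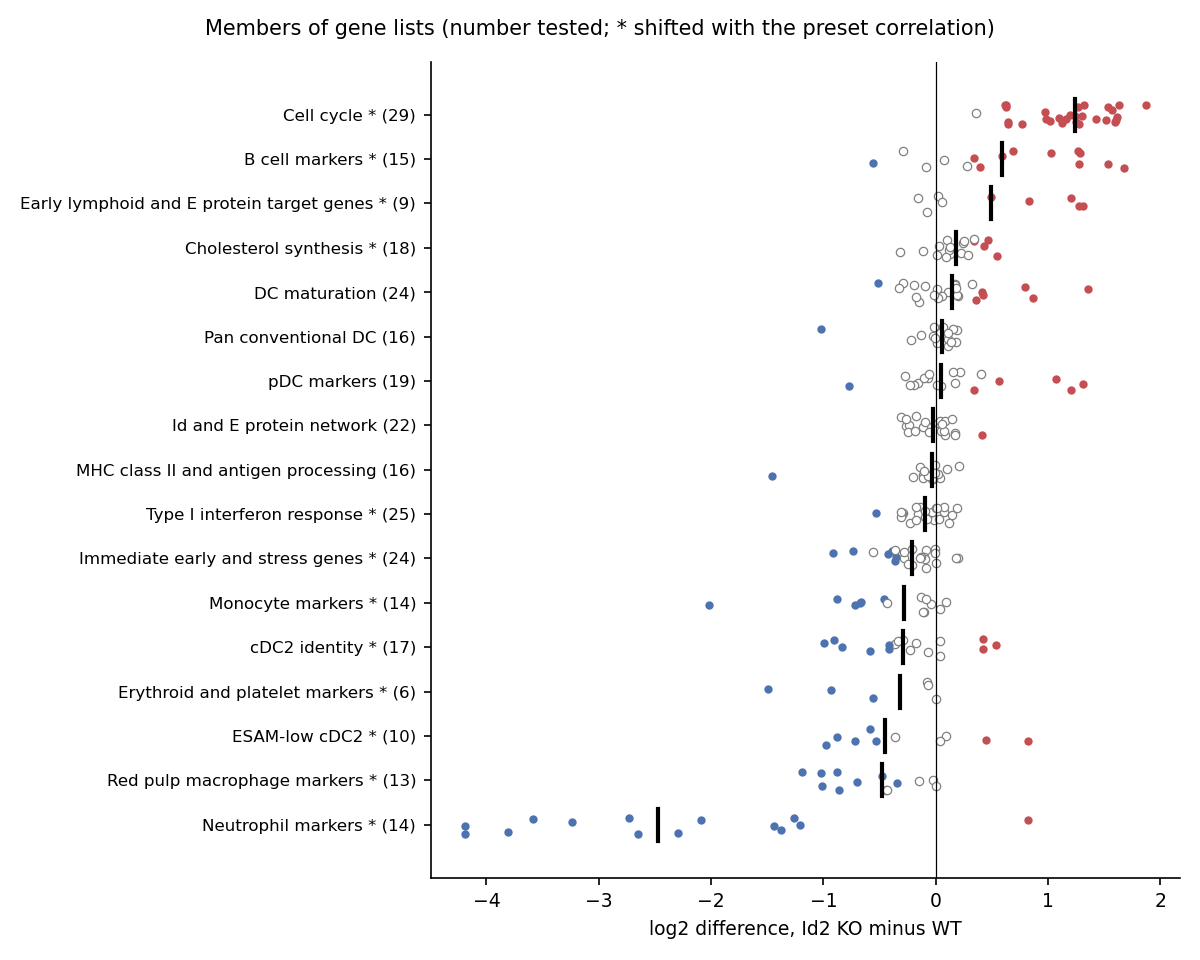
Log2 difference (arrays labelled Id2 KO minus WT) of each tested member of 17 gene lists, with a black bar at the list's median and the number tested in brackets. Filled points passed the test, red if higher and blue if lower, open points did not, a star marks the 12 lists that shifted with the preset correlation, and the medians reach from -2.47 (neutrophil) to 1.24 (cell cycle).

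Of the 28 lists tested, 12 shifted with the preset correlation, 4 up and 8 down. With an estimated correlation 0 passed (lowest adjusted p = 0.334, 2 lists at an unadjusted p below 0.05), and with fry 0 passed (12 lists at an unadjusted p below 0.05). Of the 132 list members that changed, 77 passed with each of the 4 arrays left out in turn.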

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

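The fit without X- and Y-linked genes and the crossed replicate block were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 962 under the filters, probe set summaries, scalings, priors, array weights and replicate blocks, from 684 with the replicate block to 1380 with the crossed one, and no call of a named gene or list reversed, while differences near 0 that did not pass, such as that of Zeb2 (0.04 as reported, -0.01 with median-centred arrays), changed sign. Centring on the medians gave 470 lower genes against 301, with 573 higher, and moved the median difference of the tested genes from 0.00714 to -0.05. A stricter test gave fewer genes by construction, with 328 changed, 238 higher and 90 lower in limma's treat against a fold of 1.2, and 177, 137 and 40 with a fold of at least 2. An adjusted p threshold of 0.1 gave 477 lower. With each array left out in turn, changed genes ranged from 459 (without WT replicate 1) to 1171 (without KO replicate 2), higher from 304 to 837, lower from 142 (without WT replicate 2) to 334, and the Id2 difference from -0.40 (which passed) to -0.14; the cause was not tested beyond the loss of an array. Lists shifted numbered 11 to 13 with an array left out, 17 without a filter and 8 above the 60th percentile, where 5 lists had too few members to test. With an estimated correlation they numbered 0 and with fry 0 (12 lists at an unadjusted p below 0.05 in fry). Of 51 named genes and network members, Runx1 lost its call in 3 of the left-out fits, and Zbtb16 and Mycl gained one in some. Signal over background was not given, which limits what dim genes such as Uty can show.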

Other observations

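Gene families chosen by symbol after the data were seen gave further counts in the arrays labelled Id2 KO, and some of them share members with the fixed lists, such as Kif11, Cenpe, Fcgr3 and Clec4a1. Of 34 tested histone genes, which package DNA as it is replicated, 26 rose and none fell, with a median log2 difference of 0.65 (24 with median-centred arrays, 19 without WT replicate 1). Of 17 tested centromere protein genes 12 rose and none fell (median 0.68, and 0.58 without WT replicate 1, where some calls were lost). Genes with Smc and Ncap symbols are mostly those of condensin and cohesin, which shape chromosomes, but include Smc5 and Smc6, which belong to neither. Of these 12 genes, 9 rose and none fell (median 0.60, and 0.54 without WT replicate 1, where some calls were lost). Of 30 kinesin genes 12 rose and none fell (median 0.21), with 1 lower when arrays were centred on their medians. Ribosomal protein genes counted 0 changes in limma among 40 (0 at an unadjusted p below 0.05). Of 39 genes with proteasome symbols, which include Psmc3ip although it is not a proteasome subunit, 1 rose. That call was lost without WT replicate 1, without WT replicate 2 and without KO replicate 1.

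The Fc gamma receptor genes Fcgr2b, Fcgr3 and Fcgr4, which bind IgG, all fell, with a median of -0.69, but Fcgr4 lost its call without WT replicate 1. Of 19 tested C-type lectin genes, many of them receptors for microbial sugars, 6 fell and 2 rose, with 3 lower without WT replicate 2, and the largest fall was that of Clec4e (-1.36). Fcgr4 is also in the monocyte list, and the monocyte, red pulp macrophage and neutrophil lists had medians of -0.28, -0.48 and -2.47 in the same arrays. Of the 20 tested genes nearest to Id2, 4 changed, against 8.04% of all tested genes. Rrm2 (1.09) and Adam17 (0.44) rose, and Rsad2 (-0.53) and Taf1b (-0.53) fell. Rrm2 is also in the cell cycle list and Rsad2 in the interferon list, and the count was not tested against that share.

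The tests of Xist, the pan-dendritic genes, the other splits of the arrays, the Id2 percentile and the Id2 probe set were chosen after the result was seen. The weak fall of Id2 in the arrays labelled Id2 KO has several candidate explanations. For an exchange of arrays between the groups, the other splits of the 4 arrays were tested. The highest of them gave 0 changed genes in limma against 962 (173 and 2473 at an unadjusted p below 0.05). The labelled split also separates Xist and the neutrophil genes, so this shows which arrays are alike and not which carry the Id2 genotype. An exchange of single arrays by genotype is therefore not decided, and an exchange of both whole groups would give the same 962. A signal at the floor of the array is argued against by an Id2 percentile of at least 77.0 in the arrays labelled Id2 KO. A probe set outside the deleted part, or a transcript left by the mutant allele, stays open, since the single probe set with its difference of -0.268 cannot separate them.

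The rise of B lineage genes may come from B cells among the sorted cells, which the sort should remove, or from Id2 genotype. Immunoglobulin constant-region probe sets, among the most abundant signals of B cells, differed by a median of 0.376 over 9 probe sets. The B cell genes that rose had a median of 1.15, but they were selected for rising. The whole B cell list, without that selection, had a median of 0.59. The 9 probe sets ranged from -0.04 to 1.32, and the Ighm probe set at -0.04 was dim, at log2 3.74 to 5.46. Some of the 9 are also annotated to variable-region genes. The test therefore leaves B cells open. Of the 15 tested B cell genes, 12 already lay above the filter level in both WT arrays. The filter on the mean over the 4 arrays favours such a count, so it does not show B cell RNA in the WT arrays. Genotype also stays open, because the difference of -5.28 in Xist shows that sex-linked genes differ the same way, so the effects of genotype and donor sex cannot be told apart.

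The fall of neutrophil genes may come from neutrophil RNA in the WT arrays, although the sort should remove these cells. Ngp stood at 12.26 and 12.36 in WT. A second list of 17 neutrophil genes, not looked at before, had a median of -0.465 with 12 lower in both arrays labelled Id2 KO. This misses the bounds set beforehand of -0.5 and a share of 0.75, so neutrophil RNA stays open, and Anxa3 (0.81) and Csf3r (0.82) went the other way. The 17 include genes below the filter, such as Stfa2 (3.90 in WT, difference 0.03) and Mgst1 (6.33 in WT, difference -0.94). Of the members above the filter, Cd177 (-0.91), Chil1 (-0.85), Slpi (-0.61), Ltb4r1 (-0.58), Itgb2l (-0.55), Cebpe (-0.46), Ifitm6 (-0.46) and Il1r2 (-0.43) passed in limma as lower. Anxa3 passed as higher, and Pglyrp1 (-0.26) and Mcemp1 (-0.07) did not pass. Of all tested genes, 50.7% had groups that did not overlap, in either direction. That share joins both directions and leaves out genes below the filter, so it is no direct reference for the 12 lower genes. Dilution of the other RNA by neutrophil RNA as the cause of the cell cycle rise is argued against, since the pan-dendritic genes had a median of 0.0516 (quartiles -0.02 to 0.12) against 1.24. An effect of genotype on these genes was not tested apart from donor sex.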
